A study of Homo sapiens with 4 samples.

How the data were processed

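Bone marrow mononuclear cells of healthy individuals, taken from samples described in an earlier publication, gave 4 polyadenylated RNA libraries, made with an unstranded TruSeq protocol and sequenced on a Genome Analyzer IIx, per the labels. CASAVA, Bowtie 1.0.0 and RSEM 1.2.4 are named in the submitters' processing notes with the human build hg19 (GRCh37). Bowtie is an aligner and RSEM an estimator of transcript abundance. The gene annotation and the RSEM settings are not given in the sources used here. The values the authors deposited are 1 TPM value per gene and library, and every column summed to the same total within rounding. TPM divides by transcript length and by the library total, so it keeps no record of depth, and no counting interval can be given. Of the 55872 values in a library, 56 to 276 were exactly 0, so low values are an estimate near a floor and not a count of reads. RSEM splits reads that fit several genes, so values of near-identical genes (globin pairs, immunoglobulin constant genes, pseudogenes and their parents) are uncertain. Without strand, reads of overlapping antisense genes are counted with either gene.

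Gene identifiers were matched to the GENCODE release 44 annotation lifted to GRCh37, and 53035 matched. The unmatched ones held 0.648% to 0.804% of a library's total. GC content was the median over a gene's annotated transcripts, known for 96.9% of the 14674 genes with a mean of at least 1 TPM. Coordinates are those of the annotation, counted from 1. All 4 libraries form 1 group, and no comparison between groups was possible. The labels describe separate numbered marrow samples of healthy individuals, and the spread and p-values measure only the spread between these libraries.

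Choices were made before the data were examined unless stated. Values were analysed as log2(TPM + 0.5), which understates the differences of low genes. A total of 32 gene lists were fixed, covering blood lineages and their maturation stages, other marrow cells, cell processes, genes mutated in myeloid neoplasms, and ribosomal, mitochondrial, histone and reference genes. A list's level was the mean over members with a mean of at least 1 TPM. Its SD over the libraries was compared with 10000 random lists of the same size matched on mean expression in 20 bins, which gives a one-sided permutation p no smaller than 0.0001. The Benjamini-Hochberg adjustment ran over the 30 lists with at least 5 such members, and a list was called at an adjusted p under 0.05. Genes of a list are not independent replicates, so a call describes these libraries. Differences between lists and the kappa to lambda ratio were tested with an exact two-sided sign-flip permutation test, in which at least 2 of the 16 sign flips are as large as the data. The spliceosome list's median was placed among random lists without a p. Dixon's gap ratio was computed over the libraries for list levels, ratios, library measures and each gene named in the text. Some list members had no matching symbol: CD24 of the precursor list, PECAM1 of the endothelial list, CCL3 and CCL4 of the cytokine list and 11 histone symbols.

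Genes named in the text are taken from the 20 with the highest mean, up to 4 members of each list with the highest mean and the lowest detected member, the 25 with the largest SD among genes with a mean of at least 10 TPM, the 10 with the smallest SD among those at 100 TPM or more, and the members of the planned ratios. Genes whose level can carry a person's sex or genotype (XIST, TSIX, Y-linked, histocompatibility, antigen receptor segment, killer receptor and commonly deleted genes) were left out. Not every gene the rule gives is named, and exceptions are described as chosen after their values were seen.

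The alternatives planned were other minimum levels (0.5 and 5 TPM, or 5 and 50 TPM for the 4-fold count), pseudocounts of 0.1 and 1, median-of-ratios scaling, rescaling without globin, immunoglobulin, mitochondrial and ribosomal protein genes, protein-coding genes only, the median of list members, 10 bins, the range in place of the SD, an 8-fold limit, the 100 most abundant genes, HBB alone as denominator, and each library left out. Added after seeing the data were values adjusted per library for a lowess trend (span 0.2) of log2 deviation on GC content, random lists matched on GC content in 10 bins too, the mean of spliceosome members, and the secondary and tertiary granule list without BPI. Subtracting the whole trend also removes a shift shared by all genes of a library, so the GC adjustment acts as a scaling too.

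Scripts were tested on simulated data for the list spread on 14674 genes: 0 of 150 lists without a planted shift were called, and of 50 lists of 20 genes per size, 98% were called at a shift of 0.25, 100% at 0.5 and 100% at 1 (log2). In that simulation each gene varied independently, without a GC trend or a shift shared by the genes of a library. These rates therefore need not hold for the real libraries, where genes vary together. The GC adjustment removed 99% of a planted slope. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.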

Results

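RNA from bone marrow mononuclear cells of healthy individuals was profiled in 4 libraries. Mononuclear cells are the marrow cells with a single round nucleus, chiefly lymphocytes, monocytes and immature cells of each blood lineage. The labels place all 4 libraries in 1 group. The data therefore describe which genes mononuclear cells of healthy marrow express, at what level, and how far the libraries lie apart. Each library listed 55872 genes in TPM, a length-corrected transcript abundance scaled to the same total in every library. The number of reads behind a value is therefore unknown. Values below are means ± SD over the libraries (n = 4) unless a library is named. A total of 12880 genes reached 1 TPM in every library, 11243 of them protein-coding, and the count per library was 14984 in library 1, 13503 in library 2, 14573 in library 3 and 14977 in library 4. Olfactory receptor genes, which blood cells are not known to use, had a median of 0.01 to 0.03 TPM per library (246 genes), which serves as the background level.

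The most abundant transcripts came from red cell, mitochondrial and translation genes. HBB, the adult beta globin, stood at 40259.5 ± 30676 TPM (17338, 85345, 32279.6 and 26075 TPM in libraries 1 to 4), and the alpha globins HBA1 and HBA2 at 13837 ± 4473 and 13677 ± 4825 TPM. EEF1A1, the elongation factor that brings aminoacyl-tRNA to the ribosome, reached 20715 ± 1918 TPM, and the cytochrome oxidase subunits MT-CO1, MT-CO2 and MT-CO3 reached 14026 ± 3614, 11217 ± 1242 and 11268 ± 1040.3 TPM. Of the 20 genes with the highest mean, 6 were mitochondrially encoded mRNAs, and the others included LYZ, the lysozyme of monocytes (8731 ± 3520.5 TPM), S100A9, a calcium-binding protein of myeloid cells (6922 ± 1506 TPM), B2M, the light chain of class I histocompatibility molecules (7766 ± 2333 TPM), TPT1 (7112 ± 443 TPM) and TMSB4X, which binds actin monomers (5463 ± 623 TPM). The ribosomal protein genes RPS27, RPL10 and RPS29 stood at 8725 ± 1530.5, 5309.8 ± 441 and 5228 ± 750.3 TPM. The 10 most abundant genes of a library held 15.4% ± 4.12 of its total, from 12.4% in library 1 to 21.3% in library 2.

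Red cell genes were abundant and differed in level between libraries. Globins (6 genes) spanned 4.91-fold between the highest library, library 2, and the lowest, library 1. The 15 other erythroid markers spanned 1.85-fold between the same libraries, and this order held under every scaling that kept the genes. CA1, the carbonic anhydrase of red cells, stood at 1515 ± 875 TPM, AHSP, the chaperone of free alpha globin, at 791 ± 409 TPM, and ALAS2, the erythroid enzyme that starts haem synthesis, at 305 ± 117 TPM. Of the erythroid markers, 11 ranged over more than 2-fold, among them CA1 (638, 2698, 1565 and 1159.6 TPM in libraries 1 to 4). Members went both ways in library 2, where 10 were highest and 4 were lowest. Both lists varied between libraries more than random lists of the same size and expression level (adjusted permutation p = 0.0020 for globins and 0.0272 for the markers). With values adjusted for transcript GC content the spans were 8.31-fold and 2.51-fold (adjusted permutation p = 0.0010 and 0.0010). The call for the erythroid markers ended without library 1 (adjusted permutation p = 0.249), and both calls ended with the median of members in place of the mean (adjusted permutation p = 0.0856 for globins and 0.0666 for the markers; over all alternatives 0.000725 to 0.0856 and 0.0010 to 0.249). The SD of the globin level was 0.99 as deposited, 0.53 without library 2 (adjusted permutation p = 0.0168) and 0.74 with the median, and that of the marker level 0.38 as deposited, 0.49 with the median and 0.25 without library 1 (log2).

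Fetal globin was a small part of beta-like globin. HBG1 and HBG2, the fetal gamma globin genes, together made 0.219% ± 0.0984 of the transcripts of HBB, HBD, HBG1 and HBG2, from 0.111% to 0.302%. HBD, the minor adult beta-like globin, stood at 967 ± 631 TPM and the gamma genes together at 107 ± 110.2 TPM. In libraries 1 to 4 their sum was 19.7, 264, 101 and 42.5 TPM. The cluster lies on the short arm of chromosome 11, with HBB at 5246694 to 5250625, HBD at 5253908 to 5264887 and HBG1 at 5269499 to 5271087 (GRCh37). HBG1 and HBG2 are near-identical, so reads can be split between them in either way, and the fetal share uses their sum. The globin list counts them as separate members, with ranges of 13.1-fold and 31.2-fold.

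In these mononuclear cells, granule genes of the neutrophil lineage were dominated by those made first. Whole marrow was not profiled, so the comparison holds for this fraction only. Primary granule genes, transcribed in promyelocytes, exceeded secondary and tertiary granule genes, transcribed in later precursors, by 2.98 ± 0.74 on the log2 scale, a ratio of 7.91, and were higher in 4 of 4 libraries. MPO, the myeloperoxidase of primary granules (chromosome 17, 56347216 to 56358296, GRCh37), stood at 471 ± 194 TPM, and the serine protease family members PRTN3, AZU1 and ELANE at 138 ± 33.5, 129 ± 42.6 and 121 ± 42.2 TPM, while the defensin DEFA4 was at 1.04 ± 0.471 TPM. Of the later granule genes, LCN2, an iron-siderophore binding protein, stood at 34.3 ± 16.5 TPM, LTF, the lactoferrin gene, at 27.9 ± 16.6 TPM, ARG1, the liver-type arginase, at 12.1 ± 7.62 TPM and CEACAM8 at 1.65 ± 1.01 TPM. BPI, which the list fixed beforehand holds with the later genes although its protein is stored in primary granules, stood at 14.5 ± 3.73 TPM. In the exact two-sided sign-flip permutation test, 2 of 16 sign flips gave a mean as large, the fewest that 4 libraries allow, so no result could pass 0.05. The difference was 3.83 without library 3, 4.04 with the median of members and 3.10 with BPI left out, a setting chosen after seeing the data (log2). Without library 3 the members at 1 TPM or more were chosen anew, and DEFA4 left the primary list. The 3.83 therefore reflects a change of members: with DEFA4 kept, the difference was 3.52, 2.06 and 3.65 in libraries 1, 2 and 4 (log2). The primary list spanned 2.04-fold with library 2 lowest under every scaling tried, with GC-adjusted values only just (5.6655 against 5.6739 in library 1, log2). Its spread was called as deposited (adjusted permutation p = 0.0272), and its transcripts had a median GC content of 61.3%. This call was absent with GC-adjusted values (1.13-fold, adjusted permutation p = 0.742), and without library 1, 2 or 4 (adjusted permutation p = 0.0525, 0.662 and 0.0516). The SD of its level, 0.49 as deposited, was 0.56, 0.07 and 0.54 without those libraries and 0.64 with the median of members (log2). It was also absent with random lists matched on GC content too (adjusted permutation p = 0.278) and with the median of members (adjusted permutation p = 0.0856, 0.0158 to 0.742 over all alternatives). The later list spanned 1.74-fold and was not called as deposited (adjusted permutation p = 0.24). It was called with GC-adjusted values (2.05-fold, adjusted permutation p = 0.0024), with median-of-ratios scaling (adjusted permutation p = 0.02) and without library 2 (adjusted permutation p = 0.0168, 0.0024 to 0.631 over all alternatives).

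In these mononuclear cells, monocyte genes stood above those of mature neutrophils. The 12 monocyte genes had a median of 206 TPM, led by LYZ, FCN1, a ficolin that binds microbial sugars (1199 ± 299 TPM), CTSS, a lysosomal cysteine protease (890.5 ± 112 TPM), and CD14, the lipopolysaccharide co-receptor (363 ± 86.8 TPM), with CD163, the haemoglobin scavenger receptor, lowest at 37.5 ± 16.3 TPM. Mature neutrophil genes (10 of 11 at 1 TPM or more) had a median of 4.94 TPM. CSF3R, the receptor for granulocyte colony-stimulating factor, led them at 177 ± 61.5 TPM, followed by S100P (25.5 ± 10.6 TPM) and PROK2 (15.2 ± 8.7 TPM), and the interleukin 8 receptor CXCR1 was at 1.12 ± 0.441 TPM. The spread of neither list exceeded that of matched lists (adjusted permutation p = 0.328 for monocyte and 0.396 for neutrophil genes), although the neutrophil list was called without library 2 (adjusted permutation p = 0.0273, 0.0273 to 0.835 over all alternatives).

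Dendritic cell genes had a median of 17.3 TPM, and their list varied more than matched lists. IRF8, a transcription factor of monocyte and dendritic lineages, stood at 99.51 ± 39 TPM, FCER1A, the alpha chain of the high-affinity IgE receptor, at 53.7 ± 21.3 TPM, IRF7, a factor of the type I interferon response, at 51 ± 26.2 TPM, the lectin CLEC10A at 21.3 ± 7.62 TPM and CLEC9A at 1.42 ± 0.362 TPM. The list spanned 2.44-fold between library 4 and library 2, the highest and lowest under every scaling tried (adjusted permutation p = 0.0249; 1.85-fold and p = 0.0133 with GC-adjusted values). Its call ended without library 4 (adjusted permutation p = 0.0985) or with the median of members (adjusted permutation p = 0.162, 0.0015 to 0.162 over all alternatives). The SD of its level was 0.56 as deposited, 0.50 without library 4, 0.35 without library 2 (adjusted permutation p = 0.021) and 0.47 with the median (log2). Macrophage genes were led by the iron exporter SLC40A1 (63.8 ± 13.2 TPM), the haem oxygenase HMOX1 (43.2 ± 14.7 TPM), the complement component C1QA (9.09 ± 2.38 TPM) and the scavenger receptor MARCO (8.19 ± 3.48 TPM), with CD5L at 1.25 ± 1.05 TPM (2.73, 0.28, 1.15 and 0.84 TPM in libraries 1 to 4). Among eosinophil, basophil and mast cell genes, RNASE2 and RNASE3, ribonucleases of eosinophil granules, stood at 235 ± 59.4 and 29.4 ± 8.77 TPM, CLC, the Charcot-Leyden crystal protein, at 25.1 ± 1.88 TPM, PRG2, the eosinophil major basic protein, at 16 ± 2.13 TPM, and MS4A2 at 1.02 ± 0.197 TPM. Neither of these lists varied more than matched lists (adjusted permutation p = 0.133 and 0.485).

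T cell and mature B cell genes differed by less than the spread between libraries. The difference between the list levels was 0.09 ± 0.49 on the log2 scale, with T cell genes higher in 2 and lower in 2 of the 4 libraries (exact sign-flip permutation p = 0.75, two-sided). Its sign turned with a minimum of 5 TPM (-0.21) and without library 3 (-0.12), and it was 0.51 with the median of members. At 5 TPM the low gene CR2 leaves the mature B cell list and every T cell gene stays, so that turn follows from dropping CR2. The T cell receptor chains CD3E and CD3D stood at 173 ± 58.2 and 94.1 ± 16.4 TPM, the proximal receptor kinase LCK at 81 ± 24 TPM, the adhesion receptor CD2 at 51.8 ± 9.0 TPM and the thymocyte selection factor THEMIS at 9.53 ± 2.14 TPM. CD79A and CD79B, the signalling chains of the B cell receptor, stood at 163 ± 52.9 and 161 ± 62.6 TPM, TCL1A, a co-activator of AKT kinases, at 86.9 ± 52 TPM, MS4A1, the CD20 antigen, at 65.8 ± 6.87 TPM, and the complement receptor CR2 at 2.79 ± 1.11 TPM. The mature B cell list spanned 1.97-fold with library 1 highest under every scaling tried (adjusted permutation p = 0.0272; 1.57-fold and p = 0.0305 with GC-adjusted values). Its call ended without library 1 or 4 (adjusted permutation p = 0.0764 and 0.0516) and with the median of members (adjusted permutation p = 0.0666, 0.0143 to 0.0764 over all alternatives). The SD did not shrink by much there: it was 0.48 as deposited, 0.46 and 0.51 without library 1 or 4, and 0.53 with the median, while with GC-adjusted values, which kept the call, it was 0.30 (log2). The T cell list spanned 1.78-fold and was not called as deposited (adjusted permutation p = 0.0914). It was called with GC-adjusted values (1.53-fold, adjusted permutation p = 0.024), without library 2 (adjusted permutation p = 0.0168) and with random lists matched on GC content too (adjusted permutation p = 0.00643). Median-of-ratios scaling and rescaling without the most abundant gene classes also gave a call (adjusted permutation p = 0.03 and 0.0452, 0.00643 to 0.35 over all alternatives).

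Cytotoxic lymphocyte genes included NKG7, a cytotoxic granule membrane protein (371 ± 97.48 TPM), GNLY, the pore-forming granulysin (324 ± 126 TPM), and the granzymes GZMB and GZMA (113 ± 19.7 and 109 ± 47.3 TPM), with NCAM1, the CD56 antigen of natural killer cells, lowest at 5.82 ± 1.63 TPM. The list spanned 1.61-fold with library 1 lowest under every scaling tried and was not called as deposited (adjusted permutation p = 0.24). The SD of its level was 0.29 as deposited, 0.44 with GC-adjusted values and 0.11 without library 1 (log2). It was called with GC-adjusted values (2.12-fold, adjusted permutation p = 0.0035), with median-of-ratios scaling (adjusted permutation p = 0.0045), after rescaling without the most abundant gene classes (adjusted permutation p = 0.0249) and without library 2 (adjusted permutation p = 0.0276, 0.0035 to 0.848 over all alternatives).

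Genes of B cell precursors were lowest in library 3. VPREB1, part of the surrogate light chain (chromosome 22, 22599192 to 22599927, GRCh37), was at 32.5, 23, 3.69 and 35 TPM in libraries 1 to 4, and IGLL1, its partner, at 152, 114, 36.2 and 179.9 TPM. DNTT, the terminal transferase that adds bases at V(D)J junctions, was at 51.3, 44.5, 19.9 and 63 TPM, and ARPP21 at 2.55, 2.25, 0.82 and 3.96 TPM. LEF1, a factor that T cells express too, was at 49.3, 14, 42.5 and 36 TPM and was lowest in library 2. RAG1 and RAG2, the recombinase genes, lie outside the naming rule and were chosen after their values were seen; together they stood at 9.62, 9.68, 1.42 and 12.2 TPM. Of the 11 members, 8 were lowest in library 3 and 10 ranged over more than 2-fold. The list spanned 3.1-fold between library 4 and library 3, the highest and lowest under every scaling tried (adjusted permutation p = 0.00225; 2.86-fold and p = 0.0015 with GC-adjusted values). The call ended without library 3 (adjusted permutation p = 0.50) and with the median of members (adjusted permutation p = 0.0715, 0.0010 to 0.50 over all alternatives). The SD of its level was 0.73 as deposited, 0.75 with the median and 0.34 without library 3 (log2).

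Immunoglobulin constant transcripts were abundant in every library, and plasma cell genes were detected in each. JCHAIN, which joins polymeric IgA and IgM, stood at 198 ± 32.9 TPM, XBP1, a factor of the secretory programme, at 166 ± 42.1 TPM, the endoplasmic reticulum proteins TXNDC5 and MZB1 at 112 ± 16.7 and 76.9 ± 14.4 TPM, and TNFRSF17, the BCMA receptor, at 4.09 ± 0.734 TPM. This list did not vary more than matched lists (1.46-fold, adjusted permutation p = 0.468). The constant genes IGKC, IGHA1, IGHG1 and IGLC3 stood at 3307 ± 1071, 2102 ± 924, 1759 ± 469 and 1322 ± 276 TPM, and IGHE, the IgE heavy chain, at 4.86 ± 4.15 TPM (4.44, 0.55, 3.91 and 10.5 TPM in libraries 1 to 4). Kappa stood above the summed lambda constant genes by 0.13 ± 0.19 on the log2 scale, higher in 3 of 4 libraries (exact sign-flip permutation p = 0.375, two-sided), a difference smaller than the spread between libraries. Without library 2 it was 0.21 ± 0.10, above its spread, and without library 4 it was 0.07 ± 0.18 (log2). Constant genes, with a median GC content of 61.3%, spanned 2.54-fold with library 2 lowest as deposited and library 4 lowest with GC-adjusted values (adjusted permutation p = 0.0024 as deposited). The call ended with GC-adjusted values (1.32-fold, adjusted permutation p = 0.256, 0.00075 to 0.256 over all alternatives), where the SD was 0.19 against 0.60 as deposited (log2). The call held without library 2 with an SD of 0.26 (adjusted permutation p = 0.0168) and with the median of members with an SD of 0.96 (adjusted permutation p = 0.003). It also held with random lists matched on GC content. Constant genes of 1 class are near-identical, so values of single members are uncertain.

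Stem and progenitor genes were detected at low levels in every library. MYB, a transcription factor of immature blood cells, stood at 48 ± 6.64 TPM, the protease inhibitor SPINK2 at 20.4 ± 2.84 TPM, the cell cycle kinase CDK6 at 17.4 ± 1.6 TPM, and CD34, the surface antigen used to select stem and progenitor cells, at 16.3 ± 6.66 TPM. HLF, a stem cell transcription factor, was lowest at 1.08 ± 0.185 TPM. The list spanned 1.47-fold (adjusted permutation p = 0.677). Among platelet genes, THBS1 (thrombospondin) stood at 143 ± 62.8 TPM, the chemokines PPBP and PF4 at 77.5 ± 30.4 and 25.8 ± 9.65 TPM, and the platelet tubulin TUBB1 at 24 ± 5.89 TPM. That list spanned 1.73-fold (adjusted permutation p = 0.24; 0.0478 without library 2 and 0.0478 to 0.534 over all alternatives).

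Genes of stromal, bone and fat cells were low, and their list varied between libraries. COL1A1, a chain of type I collagen, was at 1.96, 0.79, 16.9 and 8.45 TPM in libraries 1 to 4, and CXCL12, the chemokine that retains blood stem cells in marrow, was at 5.55, 4.3, 8.61 and 32.5 TPM. The matrix glycoprotein SPARC was at 22.8, 16.2, 31.8 and 28.6 TPM, and RUNX2, the bone transcription factor, at 8.71, 3.56, 10.5 and 10.2 TPM. The fat cell genes PLIN1 and ADIPOQ, outside the naming rule and chosen after their values were seen, were below 1 TPM in every library. DCN, a matrix proteoglycan, was at 1.47 ± 0.159 TPM. The list (9 of 13 genes at 1 TPM or more) spanned 2.38-fold, with library 4 highest as deposited and library 3 highest under the other scalings (adjusted permutation p = 0.0272; 1.92-fold and p = 0.0258 with GC-adjusted values). The call ended without library 3 or 4 (adjusted permutation p = 0.063 and 0.0727, 0.0148 to 0.0727 over all alternatives), while the SD was 0.65 and 0.61 against 0.62 as deposited (log2). Of 9 endothelial genes 4 reached 1 TPM, led by ENG, which myeloid cells also express (37.7 ± 18.2 TPM), with ESAM at 2.79 ± 0.686 TPM, PLVAP at 1.99 ± 0.708 TPM and CLDN5 at 1.02 ± 0.404 TPM, too few for a test. Epithelial and liver genes were led by EPCAM (13.4 ± 5.26 TPM), KRT10 (13 ± 2.44 TPM), CDH1, which erythroid precursors also express (9.59 ± 3.18 TPM), and KRT5 (5.9 ± 4.74 TPM), with KRT8 at 2.57 ± 0.431 TPM. KRT5 was at 6.34, 1.66, 3.21 and 12.4 TPM in libraries 1 to 4. The list did not vary more than matched lists (adjusted permutation p = 0.853).

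**Figure D1:**
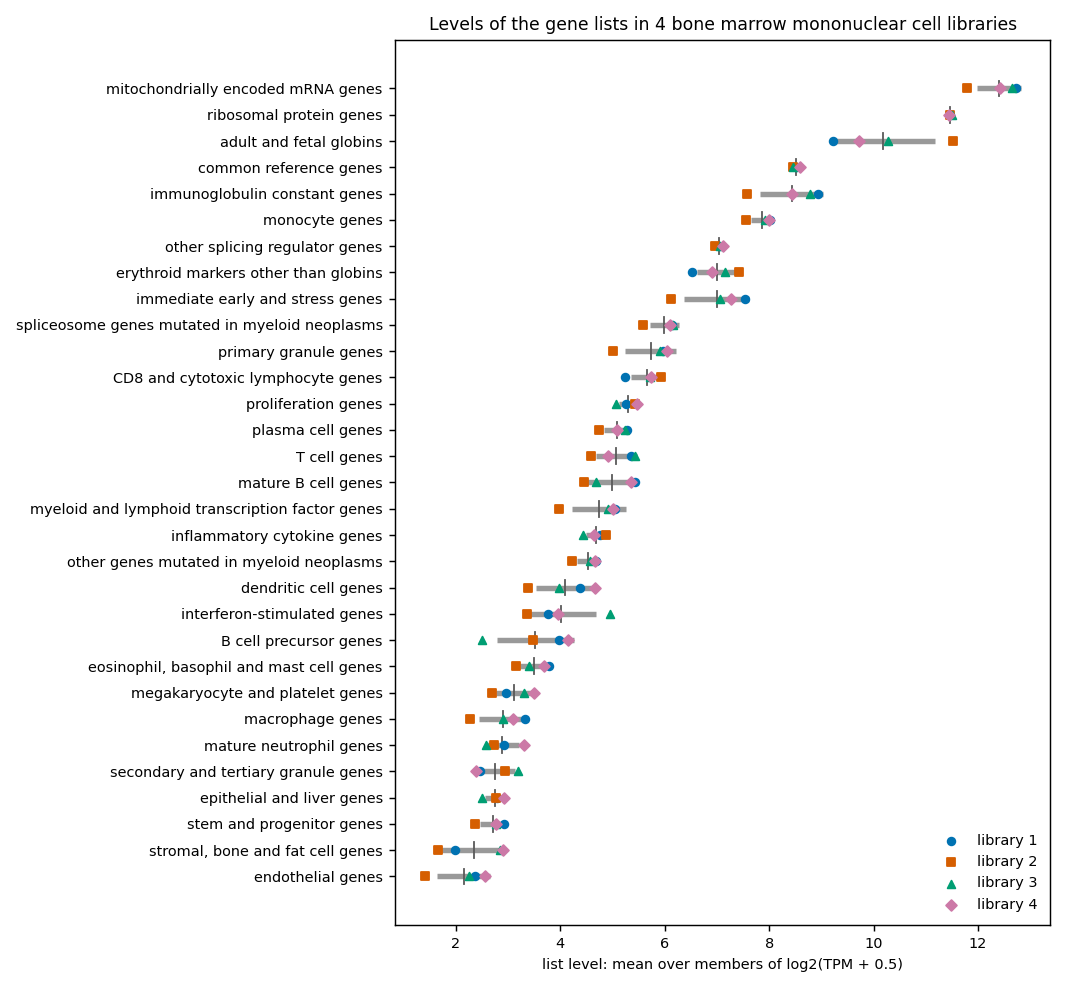
Level of each gene list (mean over its members of log2(TPM + 0.5), horizontal axis) in each of the 4 libraries (coloured points), with the mean (tick) and SD (grey bar) over libraries. Library 2 is lowest in 9 of the 12 lists that varied more than matched lists and highest in 2, the globins and the erythroid markers. With GC-adjusted values library 2 is no longer lowest for the mature B cell, immunoglobulin constant and stromal lists. For the primary granule list it is then nearly level with library 1. With median-of-ratios scaling library 2 is no longer lowest for the mature B cell list.

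Spliceosome genes that are mutated in myeloid neoplasms were expressed well above the typical gene. The median of the 11 genes was 89.2 TPM against 12 TPM over all genes at 1 TPM or more, and the list lay at percentile 100 of 10000 random lists of the same size. Splicing regulators outside that list had a higher median, 153.7 TPM, so the high level was not particular to the mutated genes. SF3B1, which recognises the branch point (chromosome 2, 198253239 to 198299803, GRCh37), stood at 198 ± 48.2 TPM, SRSF2, which binds exonic enhancers (chromosome 17, 74730197 to 74733415), at 190.4 ± 27.9 TPM, SF1 at 177 ± 57.8 TPM, U2AF2, which binds the polypyrimidine tract, at 121 ± 29.8 TPM and PRPF40B at 1.83 ± 0.672 TPM. Its spread between libraries was not above that of matched lists (1.5-fold, adjusted permutation p = 0.24; 1.13-fold and p = 0.738 with GC-adjusted values). The SD of its level was 0.28 as deposited, 0.08 with GC-adjusted values, 0.03 without library 2, 0.14 with median-of-ratios scaling and 0.49 with the median of members (log2). Library 2 stood below the mean of the others by 0.56 as deposited and 0.08 with GC-adjusted values (log2). The 26 other splicing regulators, among them HNRNPA1 (1238 ± 145 TPM), HNRNPC (622 ± 104 TPM), HNRNPK (443 ± 30.7 TPM), HNRNPA2B1 (414 ± 51.5 TPM) and TIA1 (31.2 ± 1.96 TPM), spanned 1.11-fold (adjusted permutation p = 0.954).

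Other genes mutated in myeloid neoplasms covered a wide range of levels. NPM1, a nucleolar histone chaperone, stood at 775 ± 120.2 TPM, CALR, an endoplasmic reticulum chaperone, at 409.6 ± 49.8 TPM, IDH2, the mitochondrial isocitrate dehydrogenase, at 186 ± 10.3 TPM, and RAD21, a cohesin subunit, at 96.3 ± 12.1 TPM, and 28 of 29 genes reached 1 TPM. WT1 alone did not (0.273 ± 0.090 TPM); it lies outside the naming rule and was chosen after its values were seen. The list spanned 1.37-fold (adjusted permutation p = 0.665; 0.0423 with random lists matched on GC content too and 0.0423 to 0.862 over all alternatives). Blood transcription factors were led by SPI1, the PU.1 factor of myeloid and B cells (246 ± 80.7 TPM), CEBPD (144 ± 66.1 TPM), IKZF1, the Ikaros factor (105 ± 28.3 TPM), and IRF8, with CEBPE, a factor of late granulocyte precursors, at 1.59 ± 0.661 TPM. This list, with a median GC content of 57.7%, spanned 2.1-fold with library 2 lowest under every scaling tried (adjusted permutation p = 0.0020). The call ended with GC-adjusted values (1.19-fold, adjusted permutation p = 0.136), without library 2 (adjusted permutation p = 0.563) and with the median of members (adjusted permutation p = 0.0917, 0.000725 to 0.563 over all alternatives). The SD was 0.51 as deposited, against 0.12, 0.06 and 0.60 in those settings (log2). The call held with random lists matched on GC content too.

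Interferon-stimulated genes were highest in library 3. IFI6 was at 45.2, 31.6, 176 and 47.4 TPM in libraries 1 to 4, ISG15, a ubiquitin-like modifier, at 45.1, 31.4, 78.1 and 30.8 TPM, MX2, an antiviral GTPase, at 40.1, 18.8, 54 and 37.4 TPM, IRF7 at 65.3, 14, 72.9 and 51.8 TPM and IFIT1, which binds viral RNA ends, at 3.16, 3.24, 8.99 and 3.97 TPM. IFI44L, outside the naming rule and chosen after its values were seen (chromosome 1, 79085587 to 79111830, GRCh37), was at 3.2, 4.28, 31.4 and 3.57 TPM. All 16 members reached 1 TPM, and 16 of them were highest in library 3. The list spanned 3.02-fold between library 3 and library 2, the highest and lowest under every scaling tried (adjusted permutation p = 0.0020; 2.53-fold and p = 0.0010 with GC-adjusted values). The call ended without library 3 (adjusted permutation p = 0.631, 0.000725 to 0.631 over all alternatives), with an SD of 0.31 against 0.68 as deposited (log2).

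**Figure D2:**
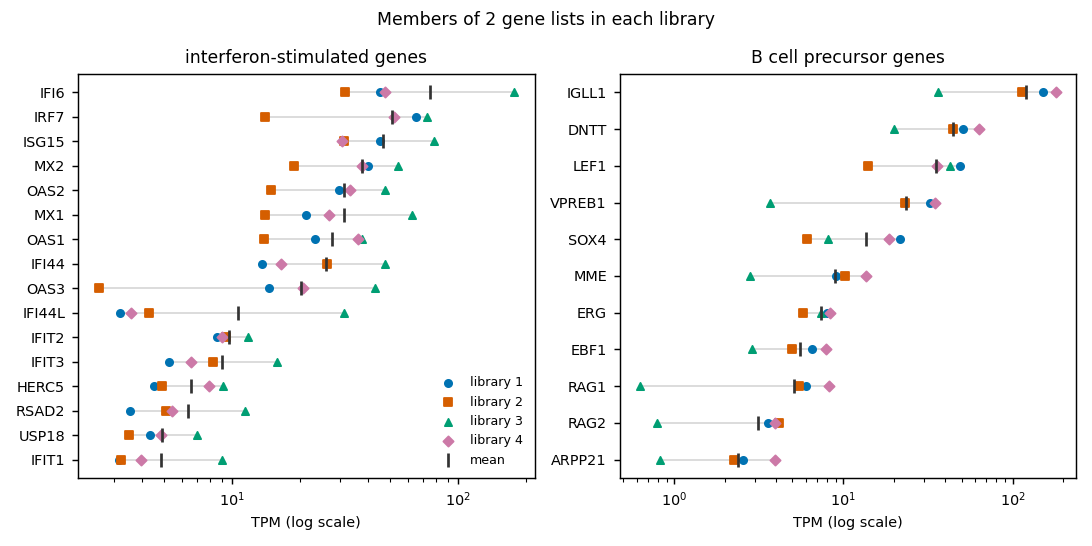
TPM (log scale) of each member of the interferon-stimulated list (left) and the B cell precursor list (right) in the 4 libraries (coloured points), with the mean over libraries (tick) and the range (grey line). Library 3 is highest for 16 of 16 interferon-stimulated genes and lowest for 8 of 11 precursor genes.

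Immediate early genes were abundant, with FOS at 971 ± 259 TPM, JUNB at 801 ± 523 TPM, the phosphatase DUSP1 at 766 ± 139.9 TPM and ZFP36, which destabilises cytokine mRNAs, at 447 ± 221 TPM, and the heat shock gene HSPA1B at 10.4 ± 5.74 TPM. The list, with a median GC content of 57.8%, spanned 2.68-fold with library 2 lowest under every scaling tried (adjusted permutation p = 0.0035). The call ended with GC-adjusted values (1.51-fold, adjusted permutation p = 0.0886) and with the median of members (adjusted permutation p = 0.0776, 0.000725 to 0.0886 over all alternatives), where the SD was 0.25 and 0.55 against 0.62 as deposited (log2). The call held without library 2, with an SD of 0.24 (adjusted permutation p = 0.0168), and with random lists matched on GC content too. Inflammatory cytokine genes included the inhibitor NFKBIA (384 ± 100.5 TPM), the chemokine CXCL8 (318 ± 226 TPM), TNFAIP3 (272 ± 87.9 TPM), IL1B (68.4 ± 48.6 TPM) and CCL2 (1.68 ± 0.994 TPM). CXCL8 was at 253, 649, 233 and 138 TPM in libraries 1 to 4. That list spanned 1.36-fold (adjusted permutation p = 0.677; 1.61-fold and p = 0.0385 with GC-adjusted values, 0.0385 to 0.93 over all alternatives). Proliferation genes were present in every library, with the sliding clamp PCNA at 199.6 ± 41 TPM, the thymidylate synthase TYMS at 104 ± 11.2 TPM, the replicative helicase subunits MCM5 and MCM2 at 93.9 ± 20.2 and 64.3 ± 12.9 TPM, and the mitotic checkpoint kinase BUB1B at 9.77 ± 1.27 TPM. The list spanned 1.32-fold and was not called as deposited (adjusted permutation p = 0.677). It was called with GC-adjusted values (1.45-fold, adjusted permutation p = 0.024), with median-of-ratios scaling (adjusted permutation p = 0.03) and without library 2 (adjusted permutation p = 0.0276, 0.024 to 0.93 over all alternatives).

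The level of the ribosomal protein list was the most even of the lists tested as deposited. Single members went both ways: library 2 was highest for 11 and lowest for 10 of the 30 genes, though none ranged over more than 2-fold. With median-of-ratios scaling the SD of the list level was 0.17 against 0.03 as deposited, with library 2 highest (log2). RPS18, RPS24, RPL13 and RPS6 stood at 4949 ± 465, 4621 ± 983, 4154 ± 685 and 3926 ± 133 TPM, RPS15 at 1329.9 ± 234 TPM, and the 30 genes spanned 1.05-fold (adjusted permutation p = 0.972; 1.47-fold and p = 0.0886 with GC-adjusted values). Common reference genes spanned 1.1-fold as a list (adjusted permutation p = 0.934). Library 2 was highest for 5 and lowest for 7 of its 15 members, and 2 members ranged over more than 2-fold. Within that list RPL13A stood at 5138 ± 376 TPM, ACTB at 3313 ± 1098 TPM and TBP at 13.6 ± 1.03 TPM. Mitochondrially encoded mRNAs held 8.43 ± 1.69% of the total, with MT-ATP6 at 8471 ± 1613 TPM and MT-ND5 lowest at 2491 ± 1124 TPM. With a median GC content of 44.3%, they spanned 1.89-fold with library 2 lowest under every scaling that kept them (adjusted permutation p = 0.0272). The call ended with GC-adjusted values (1.8-fold, adjusted permutation p = 0.0696), with median-of-ratios scaling (adjusted permutation p = 0.0798), and without library 2 (adjusted permutation p = 0.087). It also ended with random lists matched on GC content too (adjusted permutation p = 0.20) and with the median of members (adjusted permutation p = 0.0856, 0.0029 to 0.20 over all alternatives). The SD was 0.42 as deposited, 0.40 with GC-adjusted values, 0.29 with median-of-ratios scaling, 0.15 without library 2 and 0.42 with the median (log2). Histone genes whose transcripts lack poly(A) tails were below 1 TPM where matched (3 genes), with H1-5 at 0.428 ± 0.186 TPM and H4C3 at 0.42 ± 0.136 TPM.

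Most genes differed little between libraries, and library 2 lay apart. Of the 8027 genes with a mean of at least 10 TPM, 5754 (71.7%) stayed within 2-fold and 572 (7.13%) ranged over more than 4-fold, 516 of them with library 2 lowest. Without library 2 the count was 60, and with GC-adjusted values it was 158, of which 141 also ranged over 4-fold as deposited. It was 371 with median-of-ratios scaling and 115 for genes with a mean of at least 50 TPM. Library 2 was low for GC-rich genes: its median log2 deviation from the mean of the libraries went from 0.19 in the lowest GC decile to -0.97 in the highest, against -0.08 to 0.43 in library 1, -0.07 to 0.28 in library 3 and -0.04 to 0.26 in library 4. Across genes, Pearson's r of log2 TPM was 0.914 to 0.926 between library 2 and the others and 0.976 to 0.983 among the others, where genes are not independent replicates. With GC-adjusted values, taken as log2(TPM + 0.5), r was 0.949 to 0.954 and 0.978 to 0.985. The pseudocount was absent from the r of deposited values, so the rise cannot be put down to the adjustment alone. Among lists that were not called, leaving out library 2 shrank the spread of several: the SD as deposited, without library 2 and with GC-adjusted values was, for monocyte genes 0.22, 0.06 and 0.09, for macrophage genes 0.45, 0.20 and 0.17, for plasma cell genes 0.25, 0.10 and 0.11, for stem and progenitor genes 0.24, 0.10 and 0.09, and for other genes mutated in myeloid neoplasms 0.21, 0.06 and 0.09 (log2). Over the 12880 genes at 1 TPM or more in every library, the median log2 deviation was -0.21 in library 2 and 0.13 in library 4 as deposited. Median-of-ratios scaling (size factors 0.853 and 1.1) removes this shift.

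**Figure D3:**
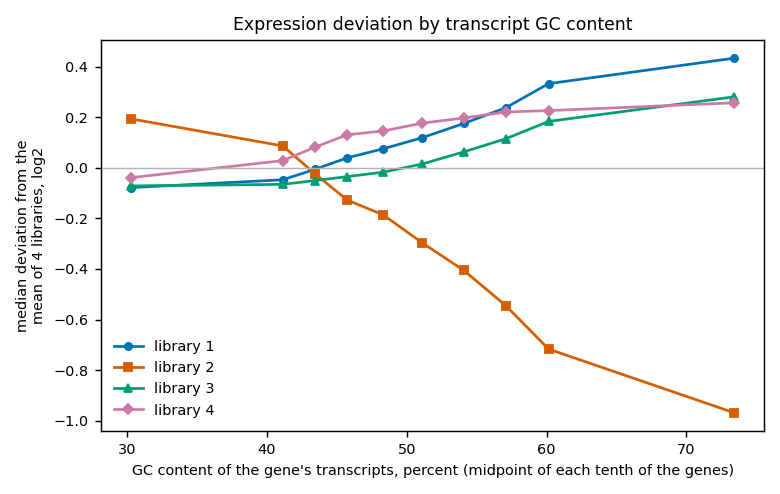
Median log2 deviation of genes from their mean over the 4 libraries (vertical axis) against the GC content of their transcripts in percent (horizontal axis, midpoint of each decile of 14224 genes), 1 line per library. The line of library 2 falls from 0.19 to -0.97, while the others end between 0.26 and 0.43.

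Of the 25 genes with the largest spread, 11 were pseudogenes, which share reads with their parent genes and are uncertain, and 10 were protein-coding. Library 2 was lowest for 7 of the protein-coding genes, among them PLEC, the cytoskeletal linker plectin (72, 3.64, 65.2 and 55.7 TPM in libraries 1 to 4), IRS2, an adaptor of the insulin receptor (45.7, 1.54, 35.1 and 28 TPM), NOTCH1, a receptor of lymphoid fate decisions (15.9, 0.78, 15.9 and 11.6 TPM), and EEIG1 (43.8, 3.04, 41.7 and 26.7 TPM). TMEM176A and TMEM176B, neighbouring membrane protein genes on chromosome 7 (150497491 to 150502206 and 150488373 to 150498448, GRCh37), stood at 17.8 ± 26.2 and 38.7 ± 59.99 TPM with SDs of 2.30 and 2.91 on the log2 scale. Library 3 carried these means: in libraries 1 to 4 TMEM176A was at 11.2, 1.01, 56.5 and 2.63 TPM and TMEM176B at 23.9, 1.02, 127 and 2.52 TPM. MYOM2, a sarcomere protein that natural killer cells also express, stood at 11.4 ± 12.9 TPM (11.3, 1.22, 3.44 and 29.7 TPM in libraries 1 to 4). As deposited, the 10 genes with the smallest spread among those at 100 TPM or more included RPL15 (2249.7 ± 41.5 TPM), the histone H3-3A (595 ± 15.9 TPM), BSG, a carrier of the Ok antigen (345 ± 8.45 TPM), SSR2 (312 ± 7.79 TPM), RSL1D1 (119 ± 2.45 TPM) and ATP6AP2 (108 ± 2.1 TPM). With GC-adjusted values the small spread was lost for some: the SD on the log2 scale went from 0.04 to 0.58 for BSG, from 0.03 to 0.26 for RPL15 and from 0.04 to 0.21 for SSR2, against a median of 0.24 over genes. It was 0.05 for RSL1D1, 0.07 for ATP6AP2 and 0.08 for H3-3A.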

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

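The tests of transcript length in library 2, of monocyte and dendritic cell genes beside the interferon-stimulated genes, and both tests of the B cell precursor genes were chosen only after the result was seen, as was the GC adjustment itself. Each value here is the gap between the highest or lowest library and its nearest neighbour, divided by the range over the 4 libraries (Dixon's ratio), where 1 library lay far from the others. Chance gives such a ratio in about 1 of 20 values. That rate does not apply to genes named for their large spread or after their values were seen, such as PLEC, IRS2, NOTCH1, RPL9P8, RPL9P9, IFI44L and RAG2. Of 220 values tested, 20 had such a ratio, 15 of them with library 2 at the end of the range. Of the 42 that were list levels, ratios and library measures, which share genes and libraries, 4 had one.

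Library 2 was lowest for the level of primary granule genes (0.869), of spliceosome genes mutated in myeloid neoplasms (0.907) and of blood transcription factors (0.889), and for the span of its deviations from the lowest to the highest GC decile (0.871). Its gaps to the mean of the others on the 3 lists were -0.97, -0.56 and -1.02 as deposited and -0.08, -0.08 and -0.23 with GC-adjusted values (log2). It was also lowest for AZU1 (0.886), CD14 (0.840), CD163 (0.849), CSF3R (0.913), IKZF1 (0.918), IRS2 (0.846), MT-ND5 (0.917), NOTCH1 (0.881), PLEC (0.911) and SF1 (0.880), and highest for S100P (0.869). Library 4 was highest for HNRNPA1 (0.830), and library 3 was highest for IFI44L (0.881) and lowest for RAG2 (0.890) and the copies RPL9P8 (0.903) and RPL9P9 (0.868).

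In library 2, 374 genes with a mean of at least 10 TPM were more than 4 times lower than the mean of the other libraries, against 11, 16 and 6 in libraries 1, 3 and 4. The tables argue against a larger share of globin and other abundant transcripts, since 284 of the 364 genes outside those classes stayed past 4-fold after rescaling without them, and against transcript length, which explained 1.8% of the variance of the deviations (6.19% after GC adjustment). GC content is a candidate explanation: the genes had a median of 61.4%, where 1000 level-matched sets had 47.7% to 52.3%, and 51 of the 374 were left after GC adjustment. The adjustment was fitted to these same deviations and also removes the shift that genes share in library 2. That shift had a median of -0.21 over genes at 1 TPM or more in every library (log2). Part of the fall to 51 was therefore built in and is not specific to GC content. What led to the GC trend, and what keeps library 2 apart after adjustment (r across genes 0.949 to 0.954 with the others, 0.978 to 0.985 among them), stays open. No biological explanation was tested for library 2.

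Interferon-stimulated genes in library 3 stood above the mean of the others by 1.26 (95% bootstrap interval over members 0.97 to 1.59) on the log2 scale, in 16 of 16 members. Such intervals, here and below, resample list members, which are not independent, and say nothing of the spread between marrow samples. GC content as the whole cause is argued against, since the gap was 1.228 after adjustment. A larger share of monocytes or dendritic cells is argued against too: the monocyte list had a gap of 0.057 (95% bootstrap interval -0.29 to 0.35) and the dendritic cell list, which shares IRF7 with the interferon-stimulated list, -0.17. Other lists were higher in library 3 too, by less: stromal genes by 0.66 (0.59 with GC-adjusted values), secondary and tertiary granule genes by 0.59 (0.53), immunoglobulin constant genes by 0.48 (0.21) and T cell genes by 0.47 (0.44). Other cell types and the handling of that sample stay open.

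B cell precursor genes in library 3 had a gap to the mean of the others of -1.36 (95% bootstrap interval over members -1.92 to -0.78) on the log2 scale, lower in 9 of 11 members. GC content as the whole cause is argued against, since the gap was -1.371 after adjustment. Fewer progenitors of every lineage are argued against, since stem and progenitor genes had a gap of 0.078 (95% bootstrap interval -0.08 to 0.23) and primary granule genes 0.23, or 0.04 and -0.00359 (interval -0.22 to 0.25) with GC-adjusted values. Other lists were lower in library 3 too: mature B cell genes had a gap of -0.39 (-0.47 with GC-adjusted values). Mature neutrophil genes, a list that shares MME with the precursor list, had -0.42. Proliferation genes had -0.31, with 15 of 16 members lower. Immunoglobulin constant genes went the other way by 0.48 (0.21) and plasma cell genes by 0.19 (0.13). What lowered the precursor genes, a lower share of precursor cells included, stays open.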

How the results depend on the processing

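GC-adjusted values, random lists matched on GC content, the mean of spliceosome members and later granule genes without BPI were chosen only after the result was seen. The number of genes ranging over 4-fold was 572 as reported, 115 at a minimum of 50 TPM, 371 with median-of-ratios scaling, 86 at 8-fold, 158 with GC-adjusted values and 60 (without library 2) to 516 with 1 library left out. The T cell against mature B cell difference turned from 0.09 to -0.2116 at a minimum of 5 TPM. There the low gene CR2 leaves the mature B cell list and every T cell gene stays, so that turn follows from dropping CR2. The difference ran from -0.124 (without library 3) to 0.2672 with 1 library left out, and the cause of that range was not tested. The spliceosome percentile, 100 as reported, was 99.94 at 5 TPM, 99.99 with median-of-ratios scaling, with protein-coding genes only and with the mean of members, 99.98 with GC-adjusted values and 99.98 to 100 with 1 library left out; the planned median equals the reported value. The 100 most abundant genes held 46.62%, by construction more than the 10 most abundant. Of 30 lists, 12 were called as reported, 3 with the median of members (of the 9 calls lost, 6 had an SD no smaller than reported), and 8 to 15 with 1 library left out. Calls were lost and gained in 5 and 5 lists with GC-adjusted values, 1 and 4 with median-of-ratios scaling, and 3 and 6 without library 2. With random lists matched on GC content too, 2 were lost and 2 gained. The 4 lists gained with median-of-ratios scaling were among the 5 gained with GC-adjusted values, so those gains are not specific to GC content. No list call changed with either pseudocount, 10 bins, the range, either minimum level, protein-coding genes only or BPI left out, where a list could still be tested. The granule difference kept its sign under the alternatives run (2.47 to 4.04), as did kappa against lambda (0.07 to 0.21), and the fetal share ran from 0.191% to 0.254%. Genes detected in every library numbered 8813 at 5 TPM to 15209 at 0.5 TPM. Named genes moved by more than 1 SD in 138 of 148 cases after rescaling without abundant genes, which by construction raises the rest. By construction the GC adjustment leaves a gene's mean over libraries nearly as it was, and a scaling leaves differences within a library so, which tests neither. Kappa against lambda has no value with protein-coding genes only, and lists made of left-out genes have none after rescaling. Depth is unknown from TPM, so no limit from counting can be given for low genes.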

Other observations

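Transcripts of the RPL9 family were divided between copies in different ways. RPL9, outside the naming rule and chosen after its values were seen, and the copies RPL9P8 and RPL9P9 together stood at 3999 ± 729 TPM (n = 4), within 1.46-fold. RPL9P8 and RPL9P9 alone ranged over 1597-fold and 1532-fold.

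Alpha against beta globin, as HBA1 plus HBA2 over HBB, stood at 0.824 ± 0.25 (n = 4), from 0.452 in library 2 to 0.981 in library 1. The GC content of the transcripts was 65.4% and 65.9% for HBA1 and HBA2 and 51% for HBB, and library 2 was low for GC-rich genes (-0.97 on the log2 scale in the highest GC decile). The summed IgG constant genes stood at 3642 ± 1386 TPM against 2249.6 ± 1005 TPM for IgA. In GC decile 10, 31% of 733 genes ranged over 4-fold, against 0.83% of 723 in GC decile 1.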
